A study of Rattus norvegicus with 7 samples.

How the data were processed

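Gene expression was measured by RNA sequencing in the thyroarytenoid muscle, which forms the body of the vocal fold, of 7 female Long Evans rats aged 8 months. Per the labels, 4 rats were wild type (WT) and 3 carried a homozygous knockout of Pink1 (Pink1-/-). Each library came from a separately numbered rat, so the animal is the replicate. Per the labels' protocols, total RNA was isolated from frozen muscle with a kit for fatty and fibrous tissue, and libraries were built with an Illumina TruSeq RNA kit. Whether the counting used strand is not given in the sources used here, so antisense and overlapping genes could not be told apart.

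Per the submitters' processing notes, RSEM and edgeR 3.9 were used by the authors. The notes give no role for either tool. The aligner, the genome build, the annotation, the filter on low genes and the scaling between libraries are not given in the sources used here. The only file used was the authors' deposited table of 1 comparison, Pink1-/- against WT, with 14702 genes. Per the file headers, the authors' deposited table gives for each gene the log2 fold change of Pink1-/- over WT, the mean log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value. CPM are counts scaled to a common total per library. No values per library were used, so the depth of each library and the precision it gives are unknown here, and spreads between animals, group means with an SD and values per rat cannot be given.

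Several properties of the table were checked. The deposited p-values equal the upper tail of a chi-square distribution with 1 degree of freedom at the likelihood ratio, with a largest relative difference of 8.29e-13. The deposited adjusted p-values equal Benjamini-Hochberg values over 14705 genes, with a largest relative difference of 3.74e-04, and the other 3 genes were not analysed here. The gene status given by the authors in the deposited table follows an adjusted p of 0.05 in all 14702 genes. Mean log2 CPM ran from -1.12 to 15.62 in the authors' deposited table, and the linear CPM summed to 1008244. A symbol was missing in 24 genes, and 161 genes shared their symbol with another gene. The symbols of 12983 genes were found in the NCBI RefSeq gene table of the rat assembly GRCr8, which was used for older names and for the order of genes along a chromosome only.

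The planned per-library analysis needed a count table, so the plan for a table without values per sample was followed: gene results are the authors' values, with no test of its own per gene. An approximate standard error (SE) of each log2 fold change was taken as its size divided by the square root of the likelihood ratio, and a 95% interval as the fold change plus or minus the normal quantile times that SE. These intervals are poor for genes near 0 counts in either genotype, where the fitted fold change also depends on the prior count and is no bound. Implied CPM per genotype was computed from the mean CPM and the fold change, assuming equal library sizes. Summed over all genes, implied CPM was 0.21 higher on the log2 scale in Pink1-/- than in WT. Scaling that made these sums equal would therefore lower every log2 fold change by about 0.21, and this was run as an alternative. As deposited, the median log2 fold change over all genes was -0.02, so the alternative puts the typical gene further below 0.

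A gene was called at an adjusted p under 0.05. Genes were named by a rule written before the data were examined: Pink1, then the 12 genes with the largest rise and the 12 with the largest fall in log2 fold change among called genes with a mean log2 CPM of at least 1 and a symbol other than a placeholder, and from each gene list up to 4 members with the smallest p. The rule also asked that all Pink1-/- values lie on the same side of all WT values, which could not be applied without values per library. In all, 40 gene lists were written at the same stage, 25 of pathways and technical signs and 15 of other cell types, and 633 of their 718 genes were found, with 5 list entries matched by an older name. Another 13 lists were written after the table was seen and were adjusted separately.

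Lists were tested with the pre-ranked version of camera in limma 3.58.1 (R 4.3.3) on the signed square root of the likelihood ratio, with a preset correlation of 0.01 between genes. The test is two-sided, compares the members with all other genes, and was adjusted by Benjamini-Hochberg over the 40 lists. Its units are genes, so its p-values do not measure the spread between rats. An estimated correlation and fry need values per library and were not run. Larger preset correlations of 0.05 and 0.1 were used in their place. The number of members called was counted over all genes and, from the deposited p-values, adjusted over the list alone. On simulated data, made by shuffling the statistics of the 14702 genes over genes 100 times, lists shifted by 0.5, 1 or 2 units of the statistic were called in the right direction in 2.75%, 40.1% and 98.5% of cases, none was called in the wrong direction, and 0.167%, 0.471% and 0.843% of unshifted lists were called. Shuffling removes any real correlation between genes, so these rates are the most favourable case. The genes next to Pink1 were compared with all other genes by Fisher's exact test. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

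Other thresholds of adjusted p and of fold change, and other numbers of genes around Pink1, were chosen beforehand and tried. Those chosen after seeing the data were likelihood ratios divided by their median excess over the chi-square expectation, a minimum mean of 1 CPM, scaling to equal summed CPM, leaving out the genes of 9 neural, glial and gland lists, and other settings of the list test, among them leaving out Myl4.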

Results

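The data were RNA sequencing libraries of the thyroarytenoid muscle from 4 WT and 3 Pink1-/- female rats aged 8 months. Pink1 encodes a mitochondrial kinase that marks damaged mitochondria for removal by mitophagy, and loss of both copies causes an inherited form of Parkinson's disease in people. The single comparison the design implies asks which genes differ in this laryngeal muscle when Pink1 is lost. All values per gene are those of the authors' deposited table, which holds 14702 genes; the depth of each library is unknown here.

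Pink1 transcripts were 30.1-fold lower in Pink1-/- than in WT muscle, a log2 fold change of -4.91 with an adjusted p of 8.24e-49 in the authors' deposited table. The 95% interval implied by the deposited likelihood ratio ran from 19.5-fold to 46.6-fold lower. Implied expression of Pink1 was 269 CPM in WT and 8.94 CPM in Pink1-/- muscle, so reads from the gene were not wholly absent from the knockout group. Values per rat were not analysed here, so the targeted gene could not be checked library by library. The tested genes on either side of Pink1 on chromosome 5, Ddost and Mul1, had adjusted p-values of 0.958 and 0.334 in the authors' deposited table. Among the 40 tested genes nearest to Pink1, 20 on each side, 1 was called (2.50%), Tcea3, against 412 of the 12904 other placed genes (3.19%), with p = 1 by a two-sided Fisher's exact test. Tcea3 was named after its value was seen.

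In the authors' deposited table, 448 of 14702 genes (3.05%) had an adjusted p under 0.05, of which 201 were higher and 247 lower in Pink1-/- muscle. The genes that rose were mostly well expressed and moved little, with a median of 2.04-fold and a median expression of 5.39 log2 CPM. The genes that fell were mostly weakly expressed and moved far, with a median of 6.33-fold and a median expression of 1.90 log2 CPM. At least a log2 fold change of 2 was reached by 16 of the genes that rose and 154 of those that fell. All 46 called genes that averaged under 1 CPM were among the lower ones. Under scaling to equal summed CPM, estimated from the same table, the split became 63 higher and 568 lower, so 9.98% of calls were rises in place of 44.9%. With likelihood ratios divided by 1.96, their median excess over the chi-square expectation, 14 genes were called, 4 higher and 10 lower; the named genes among them were Pink1, Myl4, Vip, Capn12, Gfap, Bsnd, Scg2, Calb1 and Bpifa2f.

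**Figure D1:**
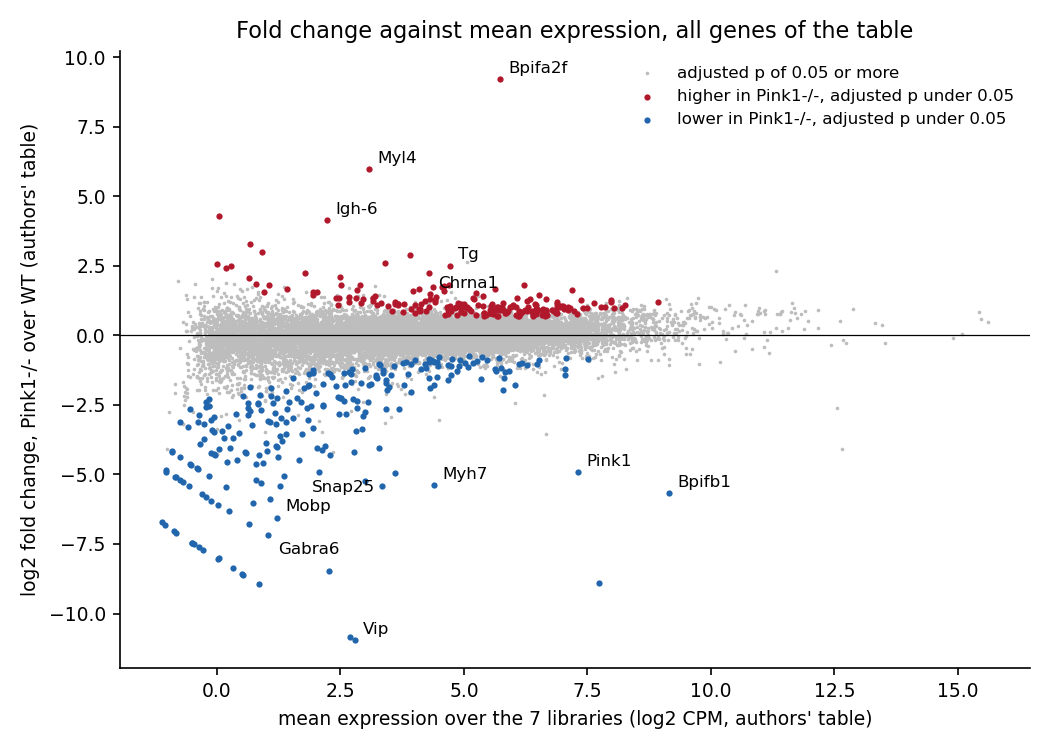
Log2 fold change of Pink1-/- over WT (vertical axis) against mean log2 CPM over the 7 libraries (horizontal axis) for the 14702 genes of the authors' deposited table, 1 point per gene. Red points are the 201 genes higher and blue points the 247 genes lower in Pink1-/- muscle at an adjusted p under 0.05; the lower genes reach further from 0 and lie at lower expression.

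Among called genes with a mean log2 CPM of at least 1 and a symbol other than a placeholder, those with the largest rises included a myosin light chain, a secreted protein and thyroglobulin. Myl4, the myosin light chain of the atria and of embryonic muscle, rose by 5.97 on the log2 scale with an adjusted p of 1.89e-37 in the authors' deposited table, from an implied 0.309 CPM in WT to 19.4 CPM in Pink1-/- muscle. Bpifa2f, a secreted protein of the BPI fold family, rose by 9.22 with an adjusted p of 8.90e-06 in the authors' deposited table, but its implied SE of 1.60 was large. Tg, the thyroid hormone precursor, rose by 2.50, Capn12, a calpain protease, by 2.90, and Bsnd, a chloride channel subunit, by 2.61 in the authors' deposited table. The authors' deposited table also lists rises of 2.09 in Ephb1, an ephrin receptor, 1.81 in Slpi, a secreted protease inhibitor, 1.81 in Prxl2b and 1.80 in Gja3, a gap junction protein. The call of Slpi ended under scaling to equal summed CPM and with a minimum of 1 CPM. Igh-6 (4.13), 7SK (2.25) and Rpl21 (2.24) complete the 12 largest rises of such genes in the authors' deposited table; each belongs to a family with near-identical copies, so reads could be split between copies and these values are uncertain.

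The largest falls were taken from called genes under the same limits. Vip, a neuropeptide of parasympathetic neurons, had a log2 fold change of -10.94 and Scg2, a protein of neurosecretory granules, of -8.46 in the authors' deposited table. Snap25, a core protein of synaptic vesicle release, stood at -5.42, Gabra6, a GABA receptor subunit of cerebellar granule cells, at -7.17, Rgs8 at -5.90 and Mobp, a myelin protein of oligodendrocytes, at -6.56 in the same authors' deposited table. Tff2, a mucus-associated trefoil peptide, fell by 8.92 and Bpifb1, a secreted protein of airway glands, fell by 5.68 in the authors' deposited table, from implied WT levels of 370 CPM and 986 CPM. Myh7, the slow and cardiac myosin heavy chain, fell by 5.38 with an adjusted p of 0.00343 in the authors' deposited table. The implied SEs of Tff2, Bpifb1 and Myh7 were large, at 1.66, 1.40 and 1.28, against a median of 0.27 over all genes. Tmem130 (-5.43), Ltk (-5.25) and Hhipl2 (-5.06) complete the 12 largest falls of such genes in the authors' deposited table. Folds of this size in weakly expressed genes depend on the prior count used in the fit and are not bounds.

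Genes of energy metabolism lay higher in Pink1-/- muscle as groups, with most single members not called. All 72 measured nuclear genes of the respiratory chain had fold changes above 0, with a median of 1.58-fold, and 11 rose while none fell. Examples from the authors' deposited table are Ndufs7 (1.11 on the log2 scale), Ndufs8 (0.93) and Ndufa11 (0.87), subunits of complex I, and Atp5mc1 (0.99), a subunit of ATP synthase. The list test gave an adjusted p of 4.96e-29, which became 4.39e-06 with a preset correlation of 0.1. When adjusted over the list alone, 54 members were called. All 19 genes of the citric acid cycle were above 0, with a median of 1.54-fold and an adjusted p of 6.29e-08 for the list, although none was called over all genes or when adjusted over the list alone. Of 25 genes of fatty acid oxidation, 24 were above 0 and 6 rose. Their median was 1.53-fold, the list's adjusted p was 2.37e-11, and 14 were called when adjusted over the list alone. Ucp3, a mitochondrial uncoupling protein of muscle, rose by 1.46, Acads, the short-chain acyl-CoA dehydrogenase, by 1.34, Pdk4, which restrains pyruvate oxidation, by 1.28, and Cpt2, of the carnitine shuttle, by 0.88 in the authors' deposited table. Glycolysis and glycogen genes had a median of 1.83-fold over 19 members, 18 above 0, with an adjusted p of 4.83e-07; none was called over all genes and 7 when adjusted over the list alone.

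The 13 protein genes carried by the mitochondrial genome had a median log2 fold change of 0.27, none was called over all genes or adjusted over the list alone, and the list's adjusted p was 0.192. Under scaling to equal summed CPM this list was called upward with an adjusted p of 0.0474, although its median fell to 0.06. Regulators of mitochondrial biogenesis lay higher over 14 members (median 0.38, adjusted p 9.42e-04), with 1 called, Esrra, a nuclear receptor for oxidative genes, at 0.88 in the authors' deposited table, and 2 when adjusted over the list alone. This list's call ended when log2 fold changes replaced likelihood ratios (adjusted p 0.0857). Markers of squamous epithelium, fibroblasts and nerve moved the opposite way in the same comparison, with median log2 fold changes of -1.20, -0.58 and -0.74. Under scaling to equal summed CPM, 71 of the 72 respiratory chain genes and 18 of the 19 citric acid cycle genes stayed above 0, but few single calls remained. They were 1 of 11 in the respiratory chain, Ndufs7, and 2 of 6 in fatty acid oxidation, Acads and Ucp3, and the call of Esrra ended.

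Genes of muscle contraction and of the motor endplate were likewise higher in Pink1-/- muscle. All 19 genes of excitation-contraction coupling were above 0, with a median of 1.88-fold and a list adjusted p of 7.46e-11; 5 rose, and 12 were called when adjusted over the list alone. Jph2, which ties the sarcoplasmic reticulum to the T-tubule, rose by 1.37, Cacnb1 and Cacng1, subunits of the muscle calcium channel, by 1.07 and 1.04, and Kcnj11, a potassium channel, by 1.01 in the authors' deposited table. Of 15 genes of the neuromuscular junction, 13 were above 0 and 2 rose. Their median was 1.58-fold, the list's adjusted p was 1.07e-06, and 11 were called when adjusted over the list alone. The 2 called over all genes were acetylcholine receptor subunits, Chrna1 at 1.47 and Chrnd at 1.06 in the authors' deposited table. Both also belong to the list of denervation and atrophy genes, in which 4 of 19 rose. The others were Fbxo32, a ubiquitin ligase of muscle atrophy, at 1.03 and Myog, a myogenic transcription factor, at 1.21 in the authors' deposited table. That list had a median of 0.35, 8 members called when adjusted over the list alone and an adjusted p of 0.00159, which became 0.0613 with a preset correlation of 0.1. The satellite cell and regeneration list had a median of 0.52 over 10 genes and an adjusted p of 0.00115, with Myog the only member called over all genes and 5 called when adjusted over the list alone. Pax7, Pax3, Calcr, Mymk and Mymx of the satellite cell and regeneration list were not found among the measured genes. Under scaling to equal summed CPM the calls of Jph2, Chrna1 and Fbxo32 remained, and those of Cacnb1, Cacng1, Kcnj11, Chrnd and Myog ended.

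The measured fibre-type genes moved in opposite directions. Myh1, Myh2 and Atp2a1 of the fast fibre list and Myl2 of the slow fibre list were not found among the measured genes. Nor were Myh13 and Myh6 of the developmental and craniofacial list. All 12 fast fibre genes were above 0 with a median of 1.94-fold and a list adjusted p of 3.44e-05; none was called over all genes and 1 when adjusted over the list alone. In the authors' deposited table Mybpc2, a fast myosin-binding protein, stood at 1.30 with an adjusted p of 0.0810. Of 13 slow fibre genes, 11 were below 0, the median was 2.07-fold lower and the list's adjusted p was 0.00159. Myh7 and Myl3 fell, the latter by 2.30 in the authors' deposited table, and 3 were called when adjusted over the list alone. Casq2, the cardiac and slow calsequestrin, stood at -1.17 with an adjusted p of 0.0883 in the authors' deposited table. Under scaling to equal summed CPM Casq2 was called, with an adjusted p of 0.0272, and so was Myh3, with 0.0381. The implied SEs of slow fibre genes were 1.97 times those of genes of like abundance. Among 6 developmental and craniofacial myosin genes only Myl4 was called over all genes. Myl4 and Myh3, embryonic myosin at -1.29 in the authors' deposited table, were called when adjusted over the list alone. The members went both ways (median 0.01), and the list's adjusted p of 0.00290 became 0.706, downward, when Myl4 was left out and 0.819 in a test on ranks.

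**Figure D2:**
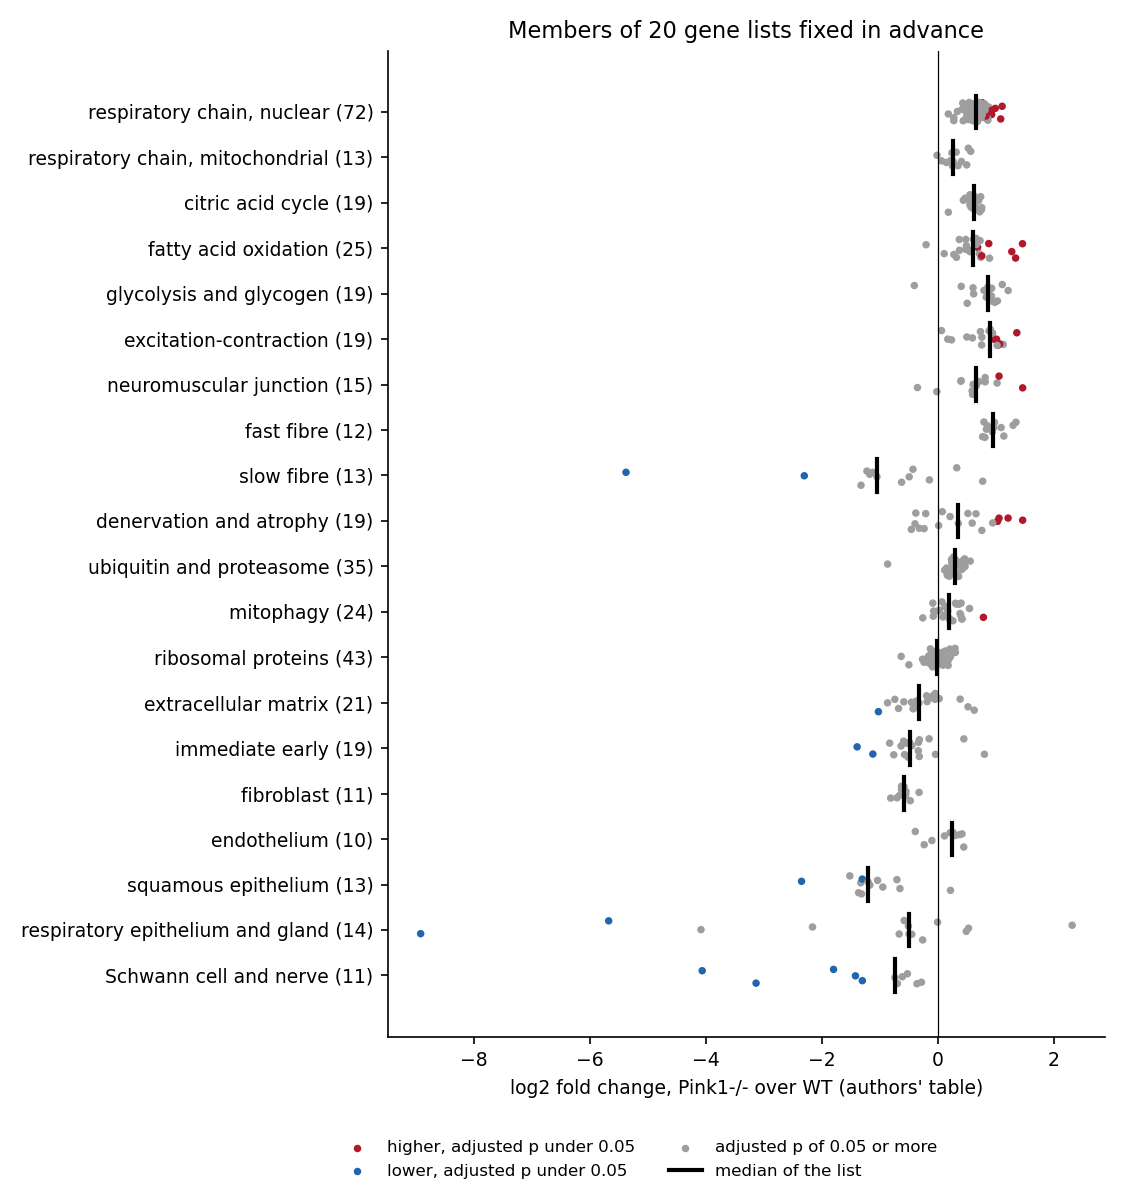
Log2 fold change of Pink1-/- over WT (horizontal axis, authors' deposited table) for the measured members of 20 gene lists fixed in advance, 1 point per gene, with the number of members in brackets and a black bar at each list's median. Red and blue points are genes called higher and lower at an adjusted p under 0.05; muscle and mitochondrial lists lie to the right of 0, and slow fibre, squamous, fibroblast and nerve lists to the left.

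Genes of the pathway in which Pink1 acts moved little. Of 24 mitophagy genes, 20 were above 0 with a median of 0.20, and 1 rose, Map1lc3a, an autophagosome protein, by 0.79 in the authors' deposited table; it was also the only member called when adjusted over the list alone. The list's adjusted p was 0.00913, but it became 0.0637 with a preset correlation of 0.05. Under scaling to equal summed CPM 11 of the 24 genes were above 0, the median was -0.01 and the call of Map1lc3a ended. Among 14 other genes of inherited Parkinson's disease, 1 rose, Park7, a redox-sensitive chaperone, by 0.82 in the authors' deposited table, with an adjusted p of 0.725 for the list; adjusted over the list alone, 2 were called higher and 3 lower. The call of Park7 also ended under that scaling. In the authors' deposited table Uchl1, a neuronal ubiquitin hydrolase, stood at -1.51 with an adjusted p of 0.109. Under the same scaling Uchl1 became called, with an adjusted p of 0.0452. Antioxidant genes had a median of 0.23 over 22 members, with none called over all genes and 4 when adjusted over the list alone. The list's adjusted p of 0.00913 became 0.0613 with a preset correlation of 0.05, and 11 of the 22 were above 0 under scaling to equal summed CPM. The mitochondrial stress response list, 17 genes with a median of 0.15, was not called (adjusted p 0.127), nor was any member, over all genes or over the list alone. Proteasome and ubiquitin genes lay slightly higher, with a median of 1.23-fold over 35 genes, 34 of them above 0, a list adjusted p of 2.88e-05 and no single call over all genes or over the list alone.

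Immune and stress signatures, as far as their genes were measured, showed few differences. Lists of interferon response (20 genes, median -0.17, adjusted p 0.363), inflammatory cytokines (8 genes, median 0.04, adjusted p 0.618) and antigen presentation (16 genes, median -0.05, adjusted p 0.972) were not called. Nor were the circadian clock (18 genes, median -0.05, adjusted p 0.618) and ribosomal proteins (43 genes, median -0.02, adjusted p 0.893). None of these lists held a called gene over all genes or adjusted over the list alone. The cytokine list lacked Il1b, Il6, Tnf, Il10 and several chemokines, which were not found among the measured genes. Its result does not cover them. Under scaling to equal summed CPM 1 ribosomal protein gene, Rpl30, became called lower, at -0.84 with an adjusted p of 0.00404. With that scaling, 5 of the 43 ribosomal protein genes and 1 of the 20 interferon genes were above 0. Immediate early genes, which answer to handling and stress, lay lower over 19 members (median -0.48, adjusted p 4.76e-04, but 0.0968 on log2 fold changes). Of the 19, 2 fell both over all genes and adjusted over the list alone, Egr1 by 1.39 and Atf3 by 1.12 in the authors' deposited table. Extracellular matrix genes had a median of -0.32 over 21 members and an adjusted p of 0.0347, which became 0.128 with a preset correlation of 0.05. Tnc, tenascin C, fell by 1.02 in the authors' deposited table, and 2 members were called when adjusted over the list alone.

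Markers of other cell types differed between the genotypes, and 4 of the 15 lists were called, all lower in Pink1-/- muscle. All 11 Schwann cell and nerve genes were below 0 (median 1.67-fold lower, adjusted p 3.82e-11); 5 fell, and 7 were called when adjusted over the list alone. In the authors' deposited table the genes that fell included Mbp (-1.30) and S100b (-1.42), of myelin and glia, and the neurofilaments Nefl (-4.06) and Nefm (-3.13). Of 13 squamous epithelium genes, 12 were below 0 (median 2.30-fold lower, adjusted p 9.08e-08). Krt13, a mucosal keratin, fell by 1.30 and Dsc3, a desmosomal cadherin, by 2.35 in the authors' deposited table, and 8 were called when adjusted over the list alone. All 11 fibroblast genes were below 0 (median 1.49-fold lower, adjusted p 0.00140, but 0.0550 on log2 fold changes) with none called over all genes or over the list alone. Respiratory epithelium and gland genes had a median of -0.50 over 14 members and an adjusted p of 0.00540, which became 0.0745 with a preset correlation of 0.1. Tff2 and Bpifb1 fell over all genes, and 1 member was called higher and 3 lower when adjusted over the list alone. In the authors' deposited table Muc5b, the main airway gel mucin and one of the most abundant transcripts, stood at -4.08 with an adjusted p of 0.150, and Bpifa1 at 2.32 with an adjusted p of 0.153.

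Genes of nervous tissue recurred among the genes lower in Pink1-/- muscle, so lists of neural cell types were written after the table was seen and tested in the same way, which makes their directions no independent evidence. All 17 pan-neuronal genes were below 0, with a median log2 fold change of -3.20, 14 called and a list adjusted p of 2.15e-25. With implied CPM below 1 set to 1, their median was -1.77. In the authors' deposited table Stmn2, a growth-associated protein of neurons, stood at -2.75 and Ina, a neuronal filament, at -6.33. Oligodendrocyte genes had a median of -2.82 with 5 of 7 called (adjusted p 3.07e-09), and genes of cerebellum and brainstem a median of -4.78 with 7 of 10 called (adjusted p 3.53e-12), among them Calb1, calbindin, at -6.77 in the authors' deposited table. Astrocyte genes had a median of -1.16 with 5 of 11 called (adjusted p 6.42e-07), led by Gfap at -3.43 in the authors' deposited table. Autonomic ganglion genes had a median of -1.23 with 5 of 10 called (adjusted p 5.84e-09), including Dbh, the noradrenaline-forming enzyme, at -3.60 and Chrna3, the ganglionic acetylcholine receptor, at -8.59 in the authors' deposited table. Choroid plexus genes (median -0.95, 2 of 5 called, adjusted p 0.00974) and forebrain genes (median -0.54, 2 of 8 called, adjusted p 0.0284) were mixed. The forebrain call ended with a preset correlation of 0.05 (adjusted p 0.0511) or 0.1 (0.0821), on ranks (0.208), with a minimum of 1 CPM (0.227) and under equal summed CPM (0.111), and the choroid plexus call on ranks (0.0565) and with a minimum of 1 CPM (0.0917). Peripheral Schwann cell genes had a median of -0.50 with 1 of 10 called (adjusted p 6.40e-05). Of the pan-neuronal genes 3, and of the peripheral Schwann cell genes 5, also stood in a list fixed in advance. Implied expression in Pink1-/- muscle reached 1 CPM for 5 of the 17 pan-neuronal and 1 of the 7 oligodendrocyte genes. It did so for 1 of the 10 cerebellum and brainstem genes and 9 of the 10 peripheral Schwann cell genes.

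**Figure D3:**
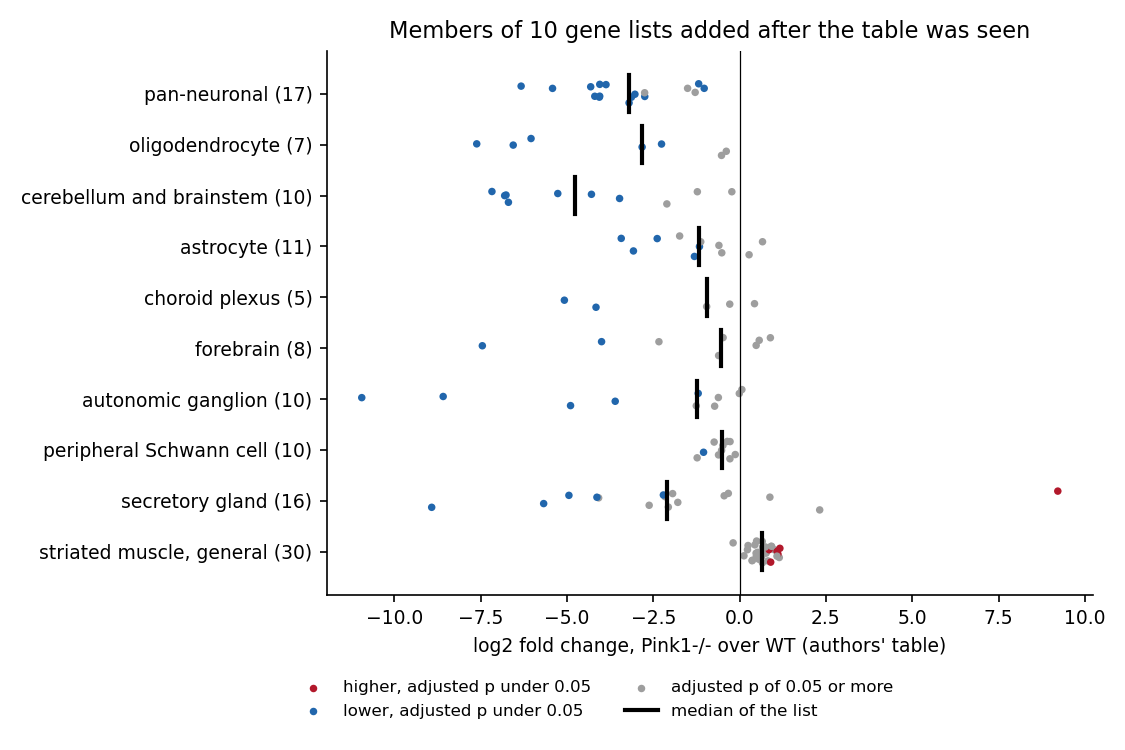
Log2 fold change of Pink1-/- over WT (horizontal axis, authors' deposited table) for the measured members of 10 gene lists written after the table was seen, 1 point per gene, with the number of members in brackets and a black bar at each list's median. Red and blue points are genes called higher and lower at an adjusted p under 0.05; pan-neuronal, oligodendrocyte and cerebellar lists have medians from -4.78 to -2.82, against -0.50 for peripheral Schwann cell genes and 0.66 for striated muscle genes.

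The remaining cell type lists were not called. Endothelium (10 genes, median 0.24, adjusted p 0.267), smooth muscle and pericytes (9 genes, median 0.17, adjusted p 0.585), and macrophages (12 genes, median 0.20, adjusted p 0.205) held no called gene. The same was true of cartilage (11 genes, median -0.51, adjusted p 0.267), mast cells (9 genes, median 0.33, adjusted p 0.721) and erythrocytes (6 genes, median 0.30, adjusted p 0.419), and in none of these was a gene called when adjusted over the list alone. T and natural killer cells (3 genes, median 0.27, adjusted p 0.387), B and plasma cells (3 genes, median 0.84, adjusted p 0.389) and neutrophils (4 genes, median -0.89, adjusted p 0.732) rested on few detected markers, with no call either. Adipocyte genes went both ways (8 genes, median -0.28 but a test direction upward, adjusted p 0.467), with 3 called higher when adjusted over the list alone and none over all genes. Among 5 thyroid and parathyroid genes Tg alone was called, over all genes and over the list alone, and the list's adjusted p was 0.124, or 0.0459 under scaling to equal summed CPM. The camera test found 21 of the 40 lists past the threshold, 14 upward and 7 downward.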

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

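Apart from the thresholds and the numbers of genes around Pink1, all alternatives were chosen after seeing the data. Counts of called genes moved most. At an adjusted p under 0.1 there were 773 genes, 406 of them higher and 367 lower in Pink1-/-; under 0.01 there were 177, 57 higher and 120 lower. A log2 fold change of at least 1 left 113 higher genes and 226 lower ones. These thresholds act by construction. Likelihood ratios divided by 1.96 left 14 genes, 4 higher and 10 lower, all 14 among the 448; this division treats any broad real difference as excess, so it is a severe bound. Scaling to equal summed CPM gave 63 higher and 568 lower genes, since it lowers every fold change by 0.21. A minimum of 1 CPM gave 377 genes, and leaving out the genes of the 9 added neural, glial and gland lists gave 373. Pink1 stayed called under every alternative run for it, with log2 fold changes from -5.12 to -4.91, and neither other number of neighbours gave a detected excess of calls around Pink1 (2 of the 100 nearest, p = 0.773 by Fisher's exact test, and none of the 20 nearest). Over 40 lists, 3 calls ended with a preset correlation of 0.05, 5 with 0.1, 1 on ranks and 6 on fold changes, while equal summed CPM added 2 and reversed none. Leaving out Myl4 turned the direction of 1 list, that of developmental and craniofacial myosins, whose median became -0.12 (adjusted p 0.706). Of the 85 called genes among the 218 named besides Pink1, 8 stayed called with divided likelihood ratios; 23 calls ended with equal summed CPM, all of them of genes higher in Pink1-/-, and 4 with a minimum of 1 CPM. The planned other normalizations, low-count filters, count tests, pseudocounts, estimated correlation, fry and leaving out each rat were not run, because no values per library were used, so no call here is known to hold without any 1 rat. No paired analysis was run, because the labels give no pairing between the separately numbered rats. Depth per library is unknown here, and whether other groupings of the 7 rats would give as many genes could not be counted.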

Other observations

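All tests and gene lists in this part were chosen after the table had been seen. Intervals are 95% and come from resampling the genes, so they treat genes as independent and do not cover the spread between rats. Further groups followed the muscle and mitochondrial rise. Among 71 mitochondrial ribosomal protein genes 70 were above 0 (median 0.47, 3 called, adjusted p 1.86e-17), and 66 remained above 0 under equal summed CPM. Coenzyme Q genes (median 0.60, 2 of 12 called, adjusted p 8.31e-06) included Coq9 at 0.98 in the authors' deposited table, and genes of branched-chain amino acid breakdown (median 0.45, 2 of 18 called, adjusted p 3.01e-07) included Bckdha at 1.02 in the authors' deposited table. General striated muscle genes had a median of 0.66 with 5 of 30 called (adjusted p 1.56e-11). Under equal summed CPM no mitochondrial ribosomal or coenzyme Q call remained, and 1 did in each of the other 2 groups, Bckdha and a striated muscle gene. Secretory gland genes had a median of -2.11 with 5 of 16 called lower and 1 called higher (adjusted p 4.84e-05), and their implied SEs were 3.26 times those of genes of like abundance.

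The first pattern is the fall of neural genes, tested with implied levels below 1 CPM set to 1 CPM, since folds near 0 counts depend on the prior count. A larger share of muscle RNA is argued against as the whole cause, because it would move neuronal and fibroblast genes alike and their medians differed by -1.19 (-2.19 to -0.63). Loss of myelinated peripheral nerve alone is likewise argued against by the difference of -1.27 (-2.39 to -0.66) between the neuronal and peripheral Schwann cell medians. Both differences cover the listed genes only. The neuronal list was written after neural genes were seen among the falls, which can deepen its median. Over the 5 neuronal genes that reached 1 CPM in Pink1-/- these differences were -0.71 (-2.17 to -0.45) and -0.77 (-2.23 to -0.29), but the fall itself decides that filter, so smaller values are built in. Nervous tissue of another kind in some WT libraries, central or ganglionic, stays open. A loss of neurons with genotype stays open for the neuronal genes only. It would not by itself lower oligodendrocyte genes, whose median was -2.82 with 5 of 7 called. Only 1 of these 7 reached an implied 1 CPM in Pink1-/-, so the size of their fall is uncertain. Implied SEs were 1.94, 1.72 and 1.55 times those of genes of like abundance for pan-neuronal, cerebellum and brainstem, and oligodendrocyte genes. For peripheral Schwann cell genes the ratio was about 1. Ratios above 1 are what a wide spread between rats or low levels in 1 genotype would give.

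The second pattern is the joint rise of muscle and mitochondrial genes. A rise specific to mitochondria is argued against, because the nuclear respiratory chain median differed from the excitation-contraction median by -0.25 (-0.36 to -0.07). For over-counting of short transcripts, the median of ribosomal protein genes minus 50% of the respiratory chain median was -0.35 (-0.42 to -0.27). Over-counting alone would not give this. It does not settle the point, since a lower share of other cell types could have lowered ribosomal protein genes too. An equal loss of share by all other cell types would move their markers alike, but the endothelial median lay 0.82 above the fibroblast median (0.46 to 0.99). What remains is that WT libraries may have held more mucosa, gland, connective tissue and nerve per unit of muscle with its vessels. It also remains possible that genotype raised the muscle and mitochondrial genes, and the table does not separate dissection from genotype. Secretory gland genes did not all go the same way: 13 of 16 were below 0 and 3 above. Among the latter was Bpifa2f, which rose by 9.22 on the log2 scale.

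The third pattern is the fall of slow fibre genes while fast fibre genes were higher. A larger share of muscle RNA in Pink1-/- libraries would raise both. The slow fibre median of -1.05 (-1.22 to -0.43) argues against it as the sole cause, but not against its acting beside a separate fall of slow fibre genes. A slower neighbouring muscle included in some WT libraries and a shift of fibre type with genotype cannot be told apart here. The implied SEs of slow fibre genes were 1.97 times (1.03 to 2.96) those of genes of like abundance. A wide spread between rats would give this. Low levels in 1 genotype would give it too, but 12 of the 13 genes reached an implied 1 CPM in Pink1-/-. Values per rat would be needed to separate a slower muscle from a shift of fibre type.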
